A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

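The data are 21 RNA sequencing libraries of Saccharomyces cerevisiae, in 8 groups and 2 series. Series 1 holds BY4741 (numbers 1 to 3), BY4741ΔP (written ΔP, 1 to 3) and Tpho84-Tcyc1 (1 to 3). Series 2 holds BY4741 (4 and 5), BY4741ΔU (written ΔU, 1 to 3), ume6Δ (1 to 3), pho4Δ (1 and 2) and pho84Δ (1 and 2). The placing of BY4741 1 to 3 in series 1 was inferred from their numbers and from the design text, since no label states it. The labels do not say what ΔP, ΔU and Tpho84-Tcyc1 alter, and no meaning was assumed for them. The design text calls the cultures independent. The growth protocol starts the 2 or 3 cultures of a strain from 1 overnight culture, so that p-values measure the spread between such cultures and not between separately made strains. RNA was prepared with a kit for yeast, and a stranded library kit was used on purified mRNA. Reads of non-coding RNAs such as SCR1 and LSR1 may thus depend on how much was carried over, which was not measured.

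The submitters named HISAT2, featureCounts and edgeR. The sources used here give no versions, settings or roles for them, and they name neither the genome build and annotation nor the strand setting used in counting, so sense and antisense reads of a gene cannot be told apart here. The deposited table holds RPM (reads per Mread, 1 Mread being 1 megaread) for 7127 features, of which 7123 had values; 4 lines, holding 110 to 163 RPM per library, were not used here. Whole reads were recovered by dividing each library by the RPM of 1 read, 0.0201 to 0.0911, and every value was whole within 0.01 reads. The recovered depth was 10.98 to 49.8 Mreads, with a median of 17.9 Mreads, so that 1 RPM stood for 10.98 to 49.8 reads. Names and neighbours of genes were taken from build R64, in which 6044 of the identifiers were found; 5 symbols stood at another place in that build, and the identifiers were kept for them.

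The design written before the table was seen assumed read counts and the edgeR quasi-likelihood test. The table holds RPM, so limma was used on log2(RPM + 1), and edgeR, DESeq2 and limma-voom on the recovered reads became alternatives. Each series was fitted by itself with 1 mean per group and with empirical Bayes variances that follow the mean. The comparison of the 2 BY4741 groups used all 21 libraries in 1 fit. Genes with at least 1 RPM in at least as many libraries as the smallest group holds were tested: 3 libraries in series 1, 2 libraries in series 2 and in the fit of all 21. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, and adjusted p under 0.05 was called. A gene is written as having risen, fallen or changed only where it was called. Levels are means ± SD of RPM over the libraries of a group, folds are log2 differences with the standard error from limma. Adding 1 RPM lowers the folds of genes near or below 1 RPM. Genes with 3 or fewer reads in every library of a group are given as levels with reads and without a fold, 3 reads being 0.0602 to 0.273 RPM.

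Gene lists were written from general knowledge before the table was seen: 22 lists, of which 18 were tested as sets. The other 4 (the study loci, their neighbours, alpha-specific genes and marker genes) were looked at gene by gene, and only some of their members are named in the report. The 18 are the PHO regulon, PHO signalling and constitutive phosphate transport, early meiotic genes, middle sporulation genes, Ume6 metabolic targets, inositol and phospholipid synthesis, the zinc regulon, the iron regulon, sulfur amino acid synthesis, amino acid genes under Gcn4, purine synthesis, cytosolic ribosomal proteins, ribosome biogenesis, environmental stress genes, respiration, glucose-repressed carbon metabolism, hexose transport, and mating genes. Sets were tested by camera from limma with a preset correlation of 0.01 between genes, adjusted over the 18 lists of a comparison. An estimated correlation and fry were alternatives. Member counts are given over all genes tested and, as "adjusted over the list alone", with adjustment over the members only. A further 4 lists (retrograde response, drug-efflux targets of Pdr1 and Pdr3, hypoxic genes, Leu3 targets) were chosen after values were seen and were not tested as sets.

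Genes to name were chosen by a rule fixed beforehand. It takes PHO84, SPL2, UME6, PHO4 and KCS1 in every comparison, and from the called genes the 8 largest rises and 8 largest falls (4 in comparisons between mutants or between the BY4741 groups) with a mean log2 of at least 3 and groups that did not overlap. It adds up to 3 members per called list, and the members of the lists looked at gene by gene, though not all of the latter are named in the report. Other genes named in the report are members of the lists, apart from GRX1, GRE1, YFL066C and LSR1, which were named after their values were seen. Paralogs with near-identical sequence (PHO11 and PHO12, COS5 and COS7, copies of Ty3, pairs of ribosomal protein genes, hexose transporters) share reads to a degree that was not measured here.

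Alternatives were other tests, scaling by TMM or RLE, other filters, other controls, replicate number as a block, and each library left out in turn. Where that left 1 library in a group, it was assumed to vary like the other groups of the fit. Overlaps of called genes between comparisons that share controls and the covariance of their log2 folds were set beside 100 simulations without differences between groups. In simulated counts with 200 changed genes among 5757 tested, the test of ΔP against BY4741 recovered 82.1% of genes changed 1.5 times, 94.0% at 2 times and 100% at 4 times, with 10 false calls. Each gene was drawn by itself there, without deviations shared by the genes of a library, so recovery and false calls in the real libraries may differ. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.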

Results

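RNA was sequenced from 21 cultures of the haploid MATa yeast strain BY4741 and of mutants derived from it, which the series title places in protein-coding and non-coding transcription at phosphate genes. The question addressed here is how RNA levels of genes in each mutant differ from those in BY4741 grown and sequenced in the same series. Series 1 held BY4741, BY4741ΔP (written ΔP) and Tpho84-Tcyc1 with n = 3 each. Series 2 held BY4741 (n = 2), BY4741ΔU (written ΔU, n = 3), ume6Δ (n = 3), pho4Δ (n = 2) and pho84Δ (n = 2). All cultures grew at 30 °C with 7.2 mM phosphate. In megareads, libraries of series 1 held 33.7, 15.8 and 49.8 (BY4741), 10.98, 19.4 and 15.3 (ΔP), and 49.5, 19.0 and 22.8 (Tpho84-Tcyc1). Those of series 2 held 15.5 and 16.1 (BY4741), 19.1, 17.9 and 12.6 (ΔU), 11.7, 18.9 and 28.0 (ume6Δ), 13.2 and 17.3 (pho4Δ), and 13.9 and 25.9 (pho84Δ). The marker genes URA3, LEU2 and MET17, which are deleted in BY4741, had 0 reads in all 21 libraries. HIS3, a marker deleted there only in part, stood at 88.7 to 204 RPM, and was higher in ΔU than in BY4741 (0.61, adjusted p = 0.00431), though not called without BY4741 number 4 (adjusted p = 0.0627). Levels are mean ± SD in RPM (reads per Mread). Values given directly before an adjusted p are log2 fold changes from limma.

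The genes named in the deletion strains were nearly without reads there. PHO4, which encodes the transcription factor that activates phosphate-responsive genes, had 1 and 2 reads in the pho4Δ libraries and 63.2 to 123 RPM in all others. UME6, whose product recruits repressors to meiotic and metabolic promoters, had 4, 0 and 2 reads in ume6Δ and 52.9 to 77.8 RPM elsewhere. PHO84, the gene of the high-affinity phosphate transporter, had 2 reads in each pho84Δ library (0.143 and 0.0771 RPM). It had 1 read in each pho4Δ library (0.0757 and 0.0577 RPM). In BY4741 PHO84 stood at 157, 135 and 76.2 RPM in series 1 and at 136 and 130 RPM in series 2. It reached 381, 306 and 426 RPM in ΔP and 250, 388 and 210 RPM in ΔU. In Tpho84-Tcyc1 it stood at 0.807, 1.42 and 1.23 RPM (40, 27 and 28 reads). The ume6Δ cultures differed among themselves, with 8.41, 83.8 and 89.8 RPM of PHO84.

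**Figure D1:**
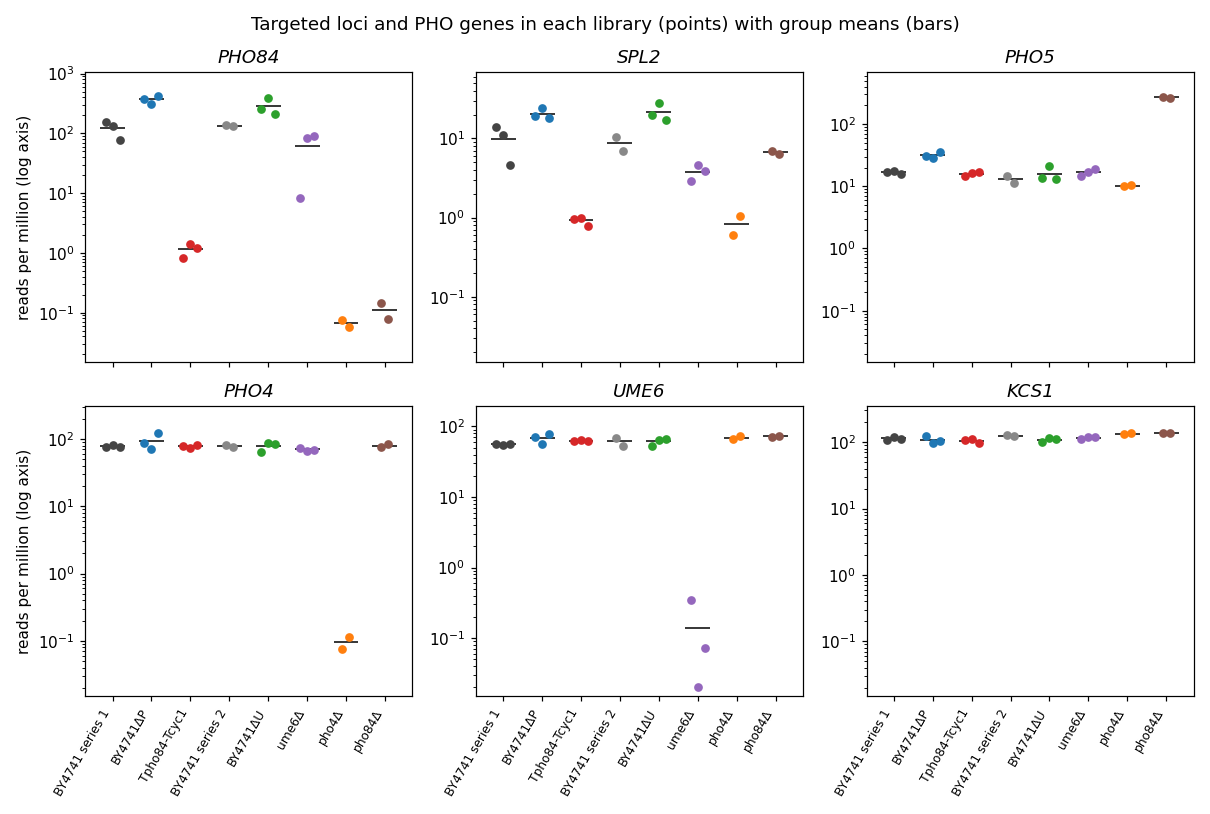
RPM in each library on a log axis for PHO84, SPL2, PHO5, PHO4, UME6 and KCS1, by group, with values under 0.02 drawn at 0.02. PHO84 ran from 0.0577 RPM in pho4Δ to 426 RPM in ΔP, and PHO5 was highest in pho84Δ, at 269 ± 10.4 RPM.

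In ΔP, phosphate-responsive genes were higher than in BY4741 of series 1. PHO84 rose from 123 ± 41.6 to 371 ± 61.0 RPM (log2 fold change 1.64, SE 0.22, adjusted p = 0.00179 in limma, n = 3 each). Next came PHO12, a gene of secreted acid phosphatase (76.4 ± 8.41 against 33.7 ± 10.7 RPM, 1.21, adjusted p = 0.00533). VTC3, a subunit of the vacuolar polyphosphate synthase, rose by a like amount (284 ± 44.2 against 127 ± 22.5 RPM, 1.17, adjusted p = 0.000814). PHO5, the main secreted acid phosphatase, rose less (31.6 ± 3.32 against 17.0 ± 0.981 RPM, 0.86, adjusted p = 0.000814), and so did its paralog PHO11 (0.98, adjusted p = 0.00298). SPL2, which encodes an inhibitor of low-affinity phosphate transport, rose from 9.80 ± 4.69 to 20.6 ± 3.36 RPM (log2 fold change 1.10, SE 0.27, adjusted p = 0.0311). Among the largest falls was that of the glucose transporter gene HXT2 (25.6 ± 1.81 against 105 ± 25.2 RPM, log2 fold change -1.97, SE 0.16, adjusted p = 8.27e-05). YGR035C (-1.98, adjusted p = 0.000675), YJL107C (-1.77, adjusted p = 0.000118) and PRM10, a membrane protein gene (5.11 ± 0.481 against 23.1 ± 4.83 RPM, -1.96, adjusted p = 6.3e-05), fell to a similar degree. UME6, PHO4 and KCS1, an inositol hexakisphosphate kinase gene, did not pass (adjusted p = 0.117, 0.383 and 0.618).

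Of 20 tested PHO regulon members, 12 rose in ΔP and 8 did not pass, or 15 rose when adjusted over the list alone (camera adjusted p = 1.47e-07, adjusted p = 0.345 with an estimated correlation). Stress genes rose in 13 of 24 cases, and 18 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.32e-06, adjusted p = 0.345 with an estimated correlation). Among them was TSL1, a subunit of trehalose synthase (0.87, adjusted p = 0.0106), whose call ended without BY4741 number 2 (adjusted p = 0.0718) or ΔP number 3 (adjusted p = 0.0525). Of 25 ribosome biogenesis genes 12 fell, or 22 adjusted over the list alone (camera adjusted p = 2.14e-15, adjusted p = 0.345 with an estimated correlation). Examples were the RNA helicase gene DBP2 (224 ± 26.3 against 490 ± 64.1 RPM, -1.12, adjusted p = 0.000907) and NSR1, of rRNA processing (-0.88, adjusted p = 0.00909; without BY4741 number 2 adjusted p = 0.0631). Hexose transporters such as HXT2 fell in 4 of 10 cases, and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.00072, adjusted p = 0.345 with an estimated correlation). With BY4741 of series 2 as the control HXT1 turned direction (0.17) and HXT3 was not called (-0.16, adjusted p = 0.356). The fall of this list thus held only in part with that control, which differs from ΔP in series as well as strain. HXT3 was also not called without BY4741 number 2 of series 1 (adjusted p = 0.0557). In sulfur amino acid synthesis 6 of 19 genes rose, the same 6 adjusted over the list alone (camera adjusted p = 0.0146, adjusted p = 0.497 with an estimated correlation). That set call ended without ΔP number 2 (adjusted p = 0.15) or number 3 (adjusted p = 0.0611).

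Across all genes of ΔP, limma called 547 of 5775, 335 higher and 212 lower, and 6 and 33 of these moved by at least 1 on the log2 scale. With RPM rescaled by TMM the split was 223 higher and 304 lower. The number called depended on single libraries: 285, 62 and 143 without BY4741 number 1, 2 and 3, and 1867 and 123 without ΔP number 2 and 3. Other rises by the rule were HAC1, the transcription factor of the unfolded protein response (726 ± 210 against 356 ± 16.4 RPM, 0.99, adjusted p = 0.00634), and DAL3, of allantoin use (28.1 ± 4.23 against 14.3 ± 1.13 RPM, 0.92, adjusted p = 0.00117). BDH2, a dehydrogenase (0.97, adjusted p = 0.0192), and PUF3, an mRNA-binding protein (1.04, adjusted p = 0.0199), also rose. Their calls ended without BY4741 number 2 (adjusted p = 0.112 and 0.116) or ΔP number 3 (0.0697 and 0.0813), for BDH2 also without BY4741 number 3 (0.0534), and for PUF3 without BY4741 number 1 (0.054). Other falls were YKR075C (-1.75), DIA1 (-1.69), the drug transporter gene AQR1 (-1.67) and RGS2, a regulator of G-protein signalling (-1.49). The SPL2 call ended without BY4741 number 2 (adjusted p = 0.0918), without BY4741 number 3 (log2 fold change 0.69, adjusted p = 0.0524) and without ΔP number 3 (adjusted p = 0.0776). It also ended with edgeR (adjusted p = 0.0611), without a filter (adjusted p = 0.0614) and with only ΔP and BY4741 in the fit (adjusted p = 0.0768).

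The choice of BY4741 cultures mattered for many genes named in ΔP. With BY4741 of series 2 as the control PHO11 was at 0.41 (adjusted p = 0.129) and HAC1 at 0.26 (adjusted p = 0.177), and neither was called. PHO84 was not called either (1.46, adjusted p = 0.0714). Its level in ΔP (380.8, 305.7 and 426.5 RPM) still lay above that control (135.9 and 130.3 RPM). That fit took its spread from all 21 libraries, ume6Δ with 8.407, 83.78 and 89.8 RPM of PHO84 among them. PRM10 (-0.41), YJL107C (-0.26), NSR1 (-0.31) and TSL1 (0.33) were not called either (adjusted p = 0.271, 0.299, 0.131 and 0.173). YGR035C (0.13), YKR075C (0.20), DIA1 (0.48), AQR1 (0.25), RGS2 (0.84) and PUF3 (-0.11) turned direction with that control, while PHO12, VTC3, PHO5, DAL3, HXT2 and DBP2 remained called. With all 5 BY4741 libraries as controls PHO84 was at 1.57 (adjusted p = 0.0542).

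In Tpho84-Tcyc1, reads of PHO84 fell from 123 ± 41.6 to 1.15 ± 0.313 RPM (log2 fold change -5.79, SE 0.22, adjusted p = 3.29e-08 in limma, n = 3 each). SPL2, the inhibitor of low-affinity transport, fell from 9.80 ± 4.69 to 0.919 ± 0.114 RPM (log2 fold change -2.38, SE 0.27, adjusted p = 0.000418). The acid phosphatase gene PHO12 fell from 33.7 ± 10.7 to 14.4 ± 1.09 RPM (-1.12, adjusted p = 0.00555). PHO5, the main acid phosphatase gene, stayed at 16.0 ± 1.22 RPM and did not pass (-0.08, adjusted p = 0.668). Among the largest rises were SOL4, a phosphogluconolactonase (to 27.5 ± 1.71 RPM, log2 fold change 1.27, SE 0.15, adjusted p = 0.000571), and the phosphoglucomutase gene PGM2 (170 ± 25.9 against 81.3 ± 3.74 RPM, 1.04, adjusted p = 0.00153). HSP26, a small heat-shock protein, rose as well (73.0 ± 3.16 against 41.1 ± 5.65 RPM, 0.82, adjusted p = 0.000585). HXT2, the glucose transporter, fell by 1.98 on the log2 scale (adjusted p = 4.04e-05). UME6, PHO4 and KCS1 did not pass (adjusted p = 0.362, 0.978 and 0.596).

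The PHO regulon in Tpho84-Tcyc1 held 8 genes that fell, 1 that rose and 11 that did not pass. Adjusted over the list alone, 10 fell and 1 rose (camera adjusted p = 6.9e-08, adjusted p = 0.211 with an estimated correlation). Those that fell included VTC3 of polyphosphate synthesis (-0.71, adjusted p = 0.0112), PHM6, of unknown function (-1.03, adjusted p = 0.0076), and PHO89, a sodium-phosphate cotransporter (-0.88, adjusted p = 0.0146). Without BY4741 number 2 these were not called (adjusted p = 0.0837, 0.0608 and 0.09), nor were VTC3 and PHO89 without Tpho84-Tcyc1 number 1 (adjusted p = 0.0518 and 0.0611) or number 3 (adjusted p = 0.0511 and 0.0718). PHO89 was at -0.15 with BY4741 of series 2 as the control (adjusted p = 0.679). The phosphatase gene PHM8 was called higher (0.40, adjusted p = 0.0449), but not without any 1 of the libraries (adjusted p of at least 0.0877) or by edgeR with TMM (adjusted p = 0.0641). Stress genes rose in 17 of 24 cases, or 21 adjusted over the list alone (camera adjusted p = 3.69e-16, adjusted p = 0.211 with an estimated correlation), among them DDR2 (1.05, adjusted p = 0.000904), TSL1 (1.00) and HSP42 (0.99). Ribosome biogenesis genes fell in 11 of 25, or 23 adjusted over the list alone (camera adjusted p = 1.27e-19, adjusted p = 0.236 with an estimated correlation), with DBP2, an RNA helicase, at -1.09 and NSR1 at -1.07. In hexose transport 4 of 10 fell, or 5 adjusted over the list alone (camera adjusted p = 0.000459, adjusted p = 0.236 with an estimated correlation). With BY4741 of series 2 as the control HXT1 turned (0.14) and HXT3 was not called (-0.24, adjusted p = 0.142). In the zinc regulon 4 of 12 fell, the same 4 over the list alone (camera adjusted p = 0.00246, adjusted p = 0.52 with an estimated correlation), but fry gave adjusted p = 0.319. With BY4741 of series 2 as the control FET4 (0.14), IZH1 (0.21) and IZH4 (0.60) turned direction. These zinc falls thus did not hold with that control, which differs from Tpho84-Tcyc1 in series as well as strain.

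For Tpho84-Tcyc1, limma called 460 of 5775 genes, 255 higher and 205 lower (160 and 324 with RPM rescaled by TMM), and 6 and 39 moved by at least 1 on the log2 scale. The number fell to 86 and 140 without BY4741 number 2 and 3, and to 153, 215 and 103 without Tpho84-Tcyc1 number 1, 2 and 3. BDH2, a dehydrogenase (1.23, adjusted p = 0.00601), the glycogen phosphorylase gene GPH1 (1.08) and the glycogen synthase gene GSY1 (0.97) were among the largest rises. YGR035C (-1.99), YJL107C (-1.98), RGS2 (-1.96), PRM10 (-1.79) and YKR075C (-1.73) fell here too, as in ΔP. SCR1, the RNA of the signal recognition particle, fell as well (-2.04, adjusted p = 0.0194). That call ended without BY4741 number 2 or 3 (adjusted p = 0.114 and 0.0819) and without Tpho84-Tcyc1 number 1, 2 or 3 (adjusted p = 0.0676, 0.0675 and 0.0585). The GSY1 call ended without BY4741 number 2 (adjusted p = 0.0608). With BY4741 of series 2 as the control, RGS2 (0.37), SCR1 (0.73), YGR035C (0.12), YKR075C (0.22) and GSY1 (-0.24) turned direction, and GPH1 (0.01) and PRM10 (-0.24) were not called.

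Compared directly, most of the genes called between ΔP and Tpho84-Tcyc1 were phosphate-responsive. PHO84 was at 371 ± 61.0 against 1.15 ± 0.313 RPM (log2 fold change 7.43, SE 0.22, adjusted p = 1.69e-09 in limma, n = 3 each). SPL2, the transport inhibitor, was higher in ΔP by 3.48 on the log2 scale (SE 0.27, adjusted p = 4.61e-05) and PHO12 by 2.33 (adjusted p = 5.63e-05). The polyphosphate synthase subunit VTC3 was higher by 1.88 (adjusted p = 3.45e-05) and its catalytic partner VTC4 by 1.20 (311 ± 56.1 against 133 ± 4.50 RPM, adjusted p = 0.000599). PHO5 was higher by 0.94 (adjusted p = 0.000789). RTC3, a stress-induced gene, was lower in ΔP (44.0 ± 3.20 against 71.2 ± 5.36 RPM, -0.68, adjusted p = 0.00392). OM14, a mitochondrial outer membrane protein (-0.60, adjusted p = 0.0344), YDR133C (-0.51, adjusted p = 0.027) and the nicotinamidase gene PNC1 (-0.50, adjusted p = 0.0376) were lower too. UME6, PHO4 and KCS1 did not pass (adjusted p = 0.783, 0.708 and 0.97).

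Of 5775 genes tested between ΔP and Tpho84-Tcyc1, 18 were called, 14 higher and 4 lower, and 546 were called without ΔP number 2. PHO regulon members made up 12 of the higher genes, and 16 of the 20 were higher adjusted over the list alone (camera adjusted p = 3.38e-34, adjusted p = 0.0104 with an estimated correlation). The other 2 higher genes, named after values were seen, were the subtelomeric YFL066C (14.9 ± 3.30 against 0.179 ± 0.0344 RPM, 3.74, adjusted p = 0.000831) and LSR1, the U2 spliceosomal RNA (1.00, adjusted p = 0.0107). LSR1 was not called without ΔP number 3 (adjusted p = 0.0697) or Tpho84-Tcyc1 number 1 or 3 (adjusted p = 0.0785 and 0.0564). In respiration 4 of 29 genes were lower adjusted over the list alone (camera adjusted p = 3e-09, adjusted p = 0.0343 with an estimated correlation), with 13 at unadjusted p under 0.05. Camera called 6 of 18 lists in all, the iron, sulfur amino acid, ribosomal protein and stress lists among them. With an estimated correlation these were not called (adjusted p = 0.689, 0.578, 0.948 and 0.244). The calls of OM14, YDR133C and PNC1 ended without ΔP number 1 (adjusted p = 0.0549, 0.0607 and 0.0815), Tpho84-Tcyc1 number 1 (0.214, 0.236 and 0.224) or Tpho84-Tcyc1 number 3 (0.241, 0.212 and 0.216). Those of OM14 and YDR133C also ended without ΔP number 3 (0.138 and 0.107), and those of OM14 and PNC1 without Tpho84-Tcyc1 number 2 (0.0705 and 0.248). With edgeR none of OM14, YDR133C and PNC1 was called (adjusted p = 0.0698, 0.0551 and 0.0539).

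Across all genes, many calls were shared by ΔP and Tpho84-Tcyc1 against BY4741 of series 1, with 142 genes lower in both and 112 higher in both, against 5 called in opposite directions. Independent lists would share 7.53 and 14.8 genes, a number that leaves out the shared controls, and simulations without group differences called too few genes to share any (at most 0). The covariance of the log2 folds over all genes was 0.0543 and lay within that of the simulations (0.0102 on average, at most 0.0720), so how much of the sharing the mutants themselves bring stays open. Shared falls included HXT2, a glucose transporter, DBP2, an RNA helicase, NSR1, PRM10 and YJL107C. The 2 comparisons share their controls, so any departure of these 3 BY4741 cultures enters both. Of the 142 shared falls, 107 were also lower in BY4741 of series 2 than in BY4741 of series 1, and of the 112 shared rises 50 were also higher there.

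**Figure D2:**
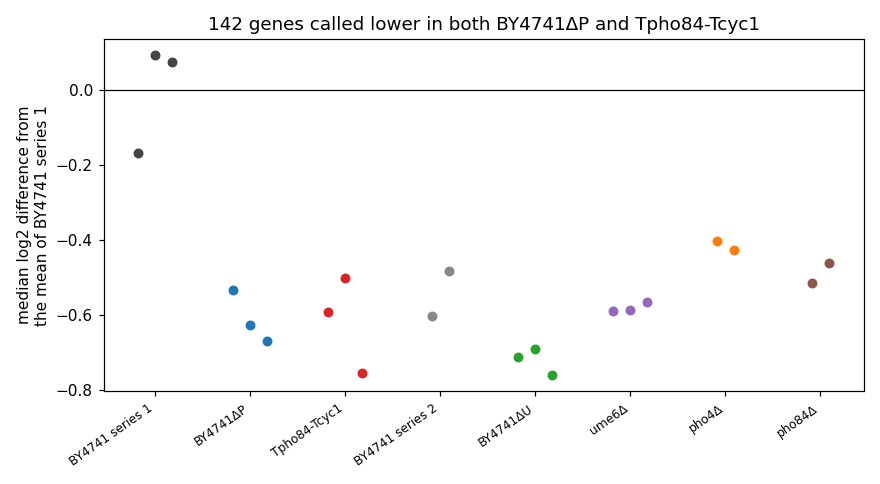
Median log2 difference from BY4741 of series 1 over the 142 genes lower in both ΔP and Tpho84-Tcyc1, for each library. Every library outside BY4741 of series 1 lay between -0.76 and -0.40, BY4741 of series 2 (-0.60 and -0.48) included.

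Among the largest rises in ΔU against BY4741 of series 2 was TIS11, which encodes an mRNA-binding protein that lowers iron-using transcripts, from 3.81 ± 3.11 to 40.7 ± 20.7 RPM (log2 fold change 3.12, SE 0.48, adjusted p = 0.000153 in limma, n = 3 against 2). Rises of similar size were seen in CRC1, a mitochondrial carnitine carrier (20.7 ± 1.54 against 1.73 ± 1.21 RPM, 3.07, adjusted p = 1.57e-07), and HMX1, haem oxygenase (21.2 ± 2.68 against 2.00 ± 0.0998 RPM, 2.88, adjusted p = 3.09e-08). HSP12, a membrane-stabilising stress protein, stood at 972 ± 22.8 against 155 ± 12.9 RPM (2.65, adjusted p = 8.51e-09), and CYB2, lactate dehydrogenase, at 31.1 ± 4.71 against 4.29 ± 1.67 RPM (2.63, adjusted p = 2.45e-07). PHO84 averaged 283 ± 93.2 against 133 ± 3.97 RPM and did not pass (log2 fold change 1.03, SE 0.67, adjusted p = 0.213), a test that takes its spread from all strains of the series, with ume6Δ number 1 at 8.41 RPM. With only ΔU and BY4741 in the fit it was called (adjusted p = 0.000404). SPL2, the transport inhibitor, rose from 8.68 ± 2.35 to 21.5 ± 5.46 RPM (log2 fold change 1.21, SE 0.21, adjusted p = 0.000403). By the naming rule, which takes genes with a mean log2 of at least 3 and no overlap between groups, the largest falls were in TIR1, a cell wall mannoprotein of hypoxia and cold (1.26 ± 0.342 against 17.0 ± 6.74 RPM, -2.95, adjusted p = 3.65e-06), and LEU1, isopropylmalate isomerase (379 ± 54.8 against 1251 ± 177 RPM, -1.72, adjusted p = 4.56e-07). UME6 and PHO4 did not pass (adjusted p = 0.969 and 1). KCS1 fell by 0.20 on the log2 scale (adjusted p = 0.0283), and its call ended without BY4741 number 4 or 5 (adjusted p = 0.122 and 0.0629) or ΔU number 1 (adjusted p = 0.0721).

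Of 24 iron regulon genes in ΔU, 21 rose, the same 21 over the list alone (camera adjusted p = 8.92e-07, adjusted p = 0.367 with an estimated correlation). They included SIT1, a siderophore transporter (2.11, adjusted p = 4.67e-05), FET3, the oxidase of iron uptake (1.72, adjusted p = 0.00077), and ISU1, a scaffold of iron-sulfur clusters (399 ± 24.1 against 140 ± 8.11 RPM, adjusted p = 3.16e-07). Stress genes rose in 21 of 24, also 21 over the list alone (camera adjusted p = 2.14e-05, adjusted p = 0.455 with an estimated correlation), such as the catalase gene CTT1 (1.55). The PHO regulon had 11 rises among 20, again 11 over the list alone (camera adjusted p = 0.0215, adjusted p = 0.607 with an estimated correlation), and the set call ended without ΔU number 2 (adjusted p = 0.082). PHM7 (1.58, adjusted p = 9.69e-06), the glycerol phosphatase gene GPP2 (318 ± 31.1 against 135 ± 1.33 RPM, 1.23, adjusted p = 1.62e-06) and PHO89 (1.65, adjusted p = 0.000387) rose, and PHO5 did not pass (0.26, adjusted p = 0.235). Each of the 25 ribosome biogenesis genes fell, 25 also over the list alone (camera adjusted p = 1.09e-22, adjusted p = 0.127 with an estimated correlation), NOP56, a snoRNP protein, by 0.78. Cytosolic ribosomal protein genes fell in 83 and rose in 3 of 137 cases, or 90 and 3 adjusted over the list alone (camera adjusted p = 3.89e-24, adjusted p = 0.418 with an estimated correlation).

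Amino acid genes under Gcn4 rose in 16 and fell in 1 of 24 in ΔU, or 18 and 1 over the list alone (camera adjusted p = 0.0309, adjusted p = 0.8 with an estimated correlation). CPA1, of arginine synthesis, stood at 1145 ± 84.0 against 365 ± 44.5 RPM (1.65, adjusted p = 3.59e-07). The Gcn4 set call ended without BY4741 number 4 (adjusted p = 0.533) or ΔU number 1 (adjusted p = 0.152). Purine synthesis fell in 8 and rose in 1 of 16, unchanged over the list alone (camera adjusted p = 0.000158, adjusted p = 0.345 with an estimated correlation), ADE17 by 0.58. Inositol and phospholipid synthesis fell in 5 of 10, also 5 over the list alone (camera adjusted p = 0.000923, adjusted p = 0.418 with an estimated correlation). INO1, inositol phosphate synthase, was at 13.7 ± 6.56 against 38.9 ± 21.5 RPM (-1.42, adjusted p = 0.00503), and its call ended without BY4741 number 4 (log2 fold change -0.84, adjusted p = 0.0983). Lists that did not pass as sets held changed genes too, in a comparison that called 49.7% of all 5840 genes (2133 higher and 771 lower). Mating genes rose in 5 and fell in 5 of 13 (6 and 5 adjusted over the list alone; camera adjusted p = 0.204), and early meiotic genes rose in 13 of 29 (12 adjusted over the list alone; camera adjusted p = 0.151). STE3, a receptor gene usually silent in MATa cells, stood at 5.17 ± 0.325 against 0.833 ± 0.650 RPM (1.80, adjusted p = 8.67e-06). These controls held only 20 and 6 reads of STE3, while BY4741 of series 1 held 2.731, 3.409 and 3.493 RPM. CYC1, iso-1-cytochrome c, stood at 98.2 ± 16.8 against 26.4 ± 8.19 RPM (1.88, adjusted p = 1.06e-06).

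The ΔU comparison called 2904 of 5840 genes in limma, 2133 higher and 771 lower, and 260 and 18 of these moved by at least 1 on the log2 scale. Rescaled by TMM, which shifted the folds by -0.137, the split was 1358 and 1396. Further rises by the rule were YER053C-A (32.9 ± 1.48 against 3.14 ± 0.131 RPM, 3.03, adjusted p = 6.03e-09), BOP2 (2.97), BDH2 (56.2 ± 12.3 against 7.12 ± 1.45 RPM, 2.81, adjusted p = 6.83e-08) and FIT2, a siderophore-binding wall protein (2.71, adjusted p = 0.000699). The FIT2 call ended with limma-voom (adjusted p = 0.0614). Further falls were ATF2, an alcohol acetyltransferase (-1.67), HES1, an oxysterol-binding protein (-1.48), and AAC3, an ADP/ATP carrier (-1.43). OAC1, an oxaloacetate carrier (-1.29), and FET4, a low-affinity iron transporter (-1.28), completed the 8 falls of the rule with INO1. ARO9, an aromatic aminotransferase gene next to SPL2, rose from 8.71 ± 0.0741 to 48.7 ± 7.82 RPM (2.34, adjusted p = 5.66e-07).

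In ume6Δ, genes known to be repressed by Ume6 rose. INO1, inositol phosphate synthase, rose from 38.9 ± 21.5 to 5375 ± 271 RPM (log2 fold change 7.19, SE 0.36, adjusted p = 1.57e-09 in limma, n = 3 against 2). HED1, a gene expressed in meiosis, reached 115 ± 2.71 RPM from 0.607 ± 0.330 RPM (6.18, adjusted p = 9.41e-12), and HOP1, a protein of the meiotic chromosome axis, 187 ± 7.08 from 1.74 ± 0.0866 RPM (6.10, adjusted p = 2.05e-11). SIP4, an activator of gluconeogenic genes, rose from 2.72 ± 0.284 to 255 ± 28.6 RPM (6.10, adjusted p = 2.9e-12). ACS1, acetyl-CoA synthetase, stood at 315 ± 23.2 against 9.01 ± 3.34 RPM (5.02, adjusted p = 5.57e-12) and CRC1, the carnitine carrier, at 91.3 ± 7.78 against 1.73 ± 1.21 RPM (5.15, adjusted p = 9.9e-11). The Ty3 element YGR109W-B stood at 39.8, 38.4 and 43.2 RPM, against 2.59 and 0.249 RPM in BY4741 (4.29, adjusted p = 4.44e-08). This element was also high in pho4Δ and pho84Δ, so its rise was not particular to ume6Δ. SPL2, the transport inhibitor, fell from 8.68 ± 2.35 to 3.77 ± 0.817 RPM (log2 fold change -1.01, SE 0.21, adjusted p = 0.00207), while PHO84 did not pass (log2 fold change -1.69, SE 0.67, adjusted p = 0.0658). It was called without ume6Δ number 1, 2 or 3 (log2 fold change -0.61, -2.20 and -2.25, adjusted p = 0.0368, 0.0272 and 0.0212), and the fold was smallest without number 1, the library with 8.41 RPM. PHO4 and KCS1 did not pass either (adjusted p = 0.356 and 0.371).

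Each of the 29 early meiotic genes rose in ume6Δ, 29 also over the list alone (camera adjusted p = 8.82e-29, adjusted p = 0.000317 with an estimated correlation). Among the largest rises were RIM4, an RNA-binding regulator of meiosis (5.15), SPO22 (5.10) and HOP2, of homologue pairing (5.80, adjusted p = 3.3e-12). Of 7 Ume6 metabolic targets 6 rose, the same over the list alone (camera adjusted p = 7.19e-07, adjusted p = 0.00905 with an estimated correlation). CAR2, ornithine aminotransferase (243 ± 13.7 against 26.0 ± 0.894 RPM, 3.17, adjusted p = 8.41e-11), CAR1, arginase (2.29, adjusted p = 8.71e-09), and POT1, a thiolase (1.07, adjusted p = 0.0249; not called without BY4741 number 4, ume6Δ number 1 or ume6Δ number 2, adjusted p = 0.202, 0.0696 and 0.06), were among them, while PHR1, a photolyase, did not pass (0.11, adjusted p = 0.564). Glucose-repressed genes rose in 8 and fell in 3 of 15, unchanged over the list alone (camera adjusted p = 0.00651, adjusted p = 0.144 with an estimated correlation). JEN1, a lactate permease (3.88), SFC1, a mitochondrial carrier (3.98), and CAT8, a transcription factor (2.41), rose. ICL1, isocitrate lyase, fell (7.39 ± 0.838 against 24.1 ± 0.414 RPM, -1.58, adjusted p = 8.76e-08). Middle sporulation genes rose in 13 and fell in 1 of 20, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.00775, adjusted p = 0.0915 with an estimated correlation), and the set call ended without BY4741 number 4 (adjusted p = 0.0663). MPC54, of the spindle pole body, was at 1.72 and SPS4 at -0.98.

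Respiration genes rose in 14 of 29 in ume6Δ, or 15 adjusted over the list alone (camera adjusted p = 0.00133, adjusted p = 0.257 with an estimated correlation), with CYC1, the cytochrome c gene, at 1.15. Stress genes rose in 12 of 24, also 12 over the list alone (camera adjusted p = 0.0337, adjusted p = 0.845 with an estimated correlation), HSP12 by 2.20. The stress set call ended without BY4741 number 5 (adjusted p = 0.253) or ume6Δ number 2 (adjusted p = 0.0769). Ribosomal protein genes fell in 58 and rose in 6 of 137, or 63 and 6 adjusted over the list alone (camera adjusted p = 2.25e-13, adjusted p = 0.444 with an estimated correlation). Ribosome biogenesis fell in 18 of 25, or 21 adjusted over the list alone (camera adjusted p = 1.02e-09, adjusted p = 0.144 with an estimated correlation), and purine synthesis in 10 of 16, or 11 adjusted over the list alone (camera adjusted p = 0.000306, adjusted p = 0.144 with an estimated correlation). PHO regulon genes split, 6 having risen and 4 fallen of 20, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.493). PHM7 was higher (3.16) and the acid phosphatase gene PHO12 lower (-0.97; not called without BY4741 number 4, adjusted p = 0.11).

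In all, limma called 2011 of 5840 genes in ume6Δ, 1349 higher and 662 lower (1207 and 941 with RPM rescaled by TMM), 401 and 23 of them by at least 1 on the log2 scale. The largest falls by the naming rule after UME6 were FET3, the iron uptake oxidase (49.6 ± 8.18 against 190 ± 98.0 RPM, -1.82, adjusted p = 0.000654), ACA1, a transcription factor (-1.68), and ICL1. SRD1 (-1.35), AAC3 (-1.31), the tRNA methyltransferase gene TRM10 (-1.30) and SIT1 (-1.25) followed. The SIT1 call ended without BY4741 number 4 (log2 fold change -0.78, adjusted p = 0.0682). ΔU and ume6Δ shared 806 rises and 335 falls, where independent lists would share 493 and 87.4 and simulations without group differences at most 18 and 7, and 131 genes were called in opposite directions. CRC1, HSP12, ARO9 (0.78 in ume6Δ) and the receptor gene STE3 (1.82 in ume6Δ) rose in both, and INO1 rose in ume6Δ and fell in ΔU. The 2 BY4741 libraries of series 2 are the controls in both comparisons, so part of such sharing can come from them. The covariance of the log2 folds was 0.104, and at most 0.0302 in the simulations.

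Set directly against ΔU, ume6Δ had higher early meiotic genes and lower iron and phosphate genes. INO1, inositol phosphate synthase, was at 5375 ± 271 against 13.7 ± 6.56 RPM (log2 fold change 8.61, SE 0.32, adjusted p = 5.01e-11 in limma, n = 3 each). HOP1, of the meiotic axis (4.61, adjusted p = 8.9e-11), SIP4 (4.88, adjusted p = 4.49e-12) and the Ty3 element YGR109W-B (5.01, adjusted p = 2.33e-09) were also higher. FET3, of iron uptake, was lower (49.6 ± 8.18 against 606 ± 183 RPM, -3.55, adjusted p = 2.62e-07), as were SIT1, a siderophore transporter (-3.36, adjusted p = 9.26e-08), and TIS11 (-3.16, adjusted p = 3.59e-05). PHO84 was at 60.7 ± 45.4 against 283 ± 93.2 RPM (log2 fold change -2.72, SE 0.60, adjusted p = 0.00184), or at a log2 fold change of -1.64 without ume6Δ number 1 (adjusted p = 1.39e-05), and SPL2 was lower by 2.23 on the log2 scale (adjusted p = 3.5e-07). Limma called 2851 of 5840 genes, 1174 higher and 1677 lower in ume6Δ (1627 and 1188 with RPM rescaled by TMM). Early meiotic genes were higher in 28 of 29, also 28 over the list alone (camera adjusted p = 1.14e-27, adjusted p = 0.000362 with an estimated correlation). The iron regulon was lower in 21 and higher in 1 of 24, unchanged over the list alone (camera adjusted p = 1.31e-07, adjusted p = 0.187 with an estimated correlation). The PHO regulon was lower in 13 and higher in 1 of 20, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.00713, adjusted p = 0.461 with an estimated correlation). Inositol and phospholipid synthesis was higher in 6 and lower in 2 of 10, unchanged over the list alone (camera adjusted p = 0.0252, adjusted p = 0.461 with an estimated correlation), and the set call ended without ΔU number 2 (adjusted p = 0.0529). PHO4 and KCS1 gave adjusted p = 0.253 and 0.151.

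In pho4Δ few genes were called against BY4741 of series 2, and phosphate genes were among the largest falls. PHO84, the high-affinity transporter, was at 0.0667 ± 0.0127 against 133 ± 3.97 RPM (1 read in each pho4Δ library, adjusted p = 0.000192 in limma, n = 2 each). SPL2, the transport inhibitor, fell from 8.68 ± 2.35 to 0.823 ± 0.306 RPM (log2 fold change -2.40, SE 0.23, adjusted p = 0.000104), and COS7, a member of a subtelomeric membrane protein family, from 20.7 ± 0.462 to 2.63 ± 0.611 RPM (log2 fold change -2.59, SE 0.12, adjusted p = 1.78e-08). PHO12, acid phosphatase, fell from 39.8 ± 7.68 to 11.3 ± 1.68 RPM (-1.72, adjusted p = 0.031) and VTC3, of polyphosphate synthesis, from 173 ± 12.6 to 82.3 ± 4.18 RPM (-1.06, adjusted p = 0.0126). QCR6, a subunit of respiratory complex III and the gene next to PHO4, fell from 140 ± 12.9 to 64.4 ± 6.22 RPM (-1.11, adjusted p = 0.000192). PHO5, the main acid phosphatase, did not pass (10.2 ± 0.320 against 13.0 ± 2.42 RPM, -0.31, adjusted p = 0.573), nor did UME6 and KCS1 (adjusted p = 0.685 and 0.675).

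The pho4Δ comparison called 13 of 5840 genes in limma, 10 lower and 3 higher, while 663 had unadjusted p under 0.05. EdgeR with TMM called 11 lower and 2 higher, and DESeq2 38 lower and 33 higher. HSP82, a chaperone (-0.63, adjusted p = 0.0203), PYK2, a pyruvate kinase (-0.55, adjusted p = 0.0203), and GRX1, a glutaredoxin (-0.46, adjusted p = 0.0379), also fell. DBP2, an RNA helicase (0.51, adjusted p = 0.0374), COS5 (0.76, adjusted p = 0.011) and YGR109W-B, of Ty3 (30.1 and 31.4 RPM, 3.91, adjusted p = 2.08e-05), rose. Of 20 PHO regulon genes 4 fell, or 11 adjusted over the list alone (camera adjusted p = 3.6e-15, adjusted p = 0.162 with an estimated correlation). Ribosome biogenesis rose in 1 of 25, or 12 adjusted over the list alone (camera adjusted p = 1.32e-13, adjusted p = 0.162 with an estimated correlation). Of 24 stress genes 0 passed over all genes, 10 were lower adjusted over the list alone, and 13 were lower at unadjusted p under 0.05 (camera adjusted p = 3.57e-09, adjusted p = 0.351 with an estimated correlation).

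Several of these pho4Δ calls ended under an alternative. Limma-voom ended those of PHO84, PHO12 and DBP2 (adjusted p = 0.465, 0.0747 and 0.0721). With only pho4Δ and BY4741 in the fit YGR109W-B, PYK2, COS5, DBP2 and GRX1 were not called (adjusted p = 0.0643, 0.345, 0.139, 0.357 and 0.278). Empirical Bayes without a trend ended the calls of PHO12, VTC3, HSP82, DBP2 and GRX1 (adjusted p = 0.158, 0.098, 0.133, 0.168 and 0.136), and all 21 libraries in 1 fit those of HSP82, PYK2, DBP2 and GRX1 (adjusted p = 0.231, 0.284, 0.284 and 0.488). DBP2 was also not called by edgeR with RLE or TMM or with RPM rescaled by TMM (adjusted p = 0.0696, 0.0697 and 0.0614). A library left out leaves 1 in its group, which is then assumed to vary like the other groups of the fit. Without BY4741 number 4 the calls of PHO12, HSP82 and DBP2 ended (adjusted p = 0.0631, 0.0508 and 0.0715). Without BY4741 number 5 those of PHO12, VTC3, HSP82, PYK2, COS5 and GRX1 ended (adjusted p = 0.0742, 0.068, 0.0758, 0.068, 0.0742 and 0.161). PHO12, DBP2 and GRX1 were not called without pho4Δ number 1 (adjusted p = 0.0848, 0.0577 and 0.105). PHO12, VTC3, HSP82, PYK2, DBP2, COS5 and GRX1 were not called without pho4Δ number 2 (adjusted p = 0.128, 0.0732, 0.193, 0.324, 0.441, 0.131 and 0.36). Without a filter PHO12, VTC3, HSP82, GRX1 and DBP2 were not called (adjusted p = 0.127, 0.0712, 0.0712, 0.0712 and 0.0887). With all 5 BY4741 libraries as controls VTC3, GRX1, HSP82, PYK2 and DBP2 were not called (adjusted p = 0.0906, 0.0906, 0.426, 0.587 and 0.708). The number called was 63, 7, 39 and 6 without BY4741 number 4 and 5 and pho4Δ number 1 and 2.

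In pho84Δ, PHO84 had 2 reads per library (adjusted p = 0.00014 in limma, n = 2 each), and genes of phosphate uptake and release rose. PHO5, the main secreted acid phosphatase, rose from 13.0 ± 2.42 to 269 ± 10.4 RPM (log2 fold change 4.28, SE 0.19, adjusted p = 1.51e-08). PHO89, the sodium-phosphate cotransporter, rose from 0.983 ± 0.0719 to 32.7 ± 1.30 RPM (log2 fold change 4.09, SE 0.32, adjusted p = 1.13e-05), and GIT1, a permease of glycerophosphoinositol, from 2.06 ± 0.0778 to 14.3 ± 3.05 RPM (2.31, adjusted p = 1.17e-05). PHO11, acid phosphatase (44.0 ± 3.46 against 15.2 ± 0.120 RPM, 1.47, adjusted p = 0.0055), and PHM6 (1.87, adjusted p = 5.85e-05) rose as well. SPL2, the transport inhibitor, did not pass (6.70 ± 0.367 against 8.68 ± 2.35 RPM, -0.31, adjusted p = 0.618), and neither did VTC3 (-0.29, adjusted p = 0.511) or PHO12 (0.81, adjusted p = 0.329). Outside the phosphate genes, HSP26, a small heat-shock protein, rose from 22.4 ± 1.87 to 123 ± 15.4 RPM (2.40, adjusted p = 1.17e-05) and the wall mannoprotein gene HPF1 by 2.17 (adjusted p = 0.000372). UME6, PHO4 and KCS1 did not pass (adjusted p = 0.553, 0.951 and 0.44).

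Of 5840 genes, limma called 17 in pho84Δ, 16 higher and 1 lower, and 171 and 11 without BY4741 number 4 and pho84Δ number 2. The remaining rises included YGR109W-B, of Ty3 (30.6 and 34.2 RPM, 3.98, adjusted p = 1.17e-05), BDH2, a dehydrogenase (1.52, adjusted p = 0.000747), and GRE1, a hydrophilin (2.42, adjusted p = 4.94e-05). HXT5, a hexose transporter (1.92, adjusted p = 0.00747), and GND2, of the pentose phosphate pathway (1.26, adjusted p = 0.0261), rose too. The PHO regulon rose in 5 and fell in 1 of 20, or 8 and 1 adjusted over the list alone (camera adjusted p = 1.03e-05, adjusted p = 0.726 with an estimated correlation). Of 24 stress genes HSP26 alone rose, and 5 rose adjusted over the list alone (camera adjusted p = 0.000552, adjusted p = 0.771 with an estimated correlation), but the set call ended without BY4741 number 5 (adjusted p = 0.0852). With limma-voom the calls of PHO84, BDH2, HXT5 and GND2 ended (adjusted p = 0.396, 0.0629, 0.0654 and 0.0808), and with only pho84Δ and BY4741 in the fit those of HPF1 and GND2 (adjusted p = 0.0689 and 0.203). GND2 was also not called by edgeR with RLE or TMM, without a filter or without a trend (adjusted p = 0.0675, 0.0669, 0.0854 and 0.0689). With 1 library left out the lone one of its group is assumed to vary like the other groups. PHO11, HXT5 and GND2 were not called without pho84Δ number 2 (adjusted p = 0.102, 0.0717 and 0.192). HXT5 and GND2 were not called without pho84Δ number 1 (adjusted p = 0.168 and 0.381), nor HXT5 without BY4741 number 5 (adjusted p = 0.112).

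Direct comparison of pho4Δ with pho84Δ placed the phosphate genes lower in pho4Δ. PHO5, the acid phosphatase gene, was at 10.2 ± 0.320 against 269 ± 10.4 RPM (log2 fold change -4.59, SE 0.19, adjusted p = 2.9e-09 in limma, n = 2 each). The cotransporter gene PHO89 was lower by 4.12 on the log2 scale (adjusted p = 4.04e-06), PHM6 stood at 2.38 ± 0.175 against 19.3 ± 0.355 RPM (adjusted p = 1.66e-06) and SPL2 at 0.823 ± 0.306 against 6.70 ± 0.367 RPM (log2 fold change -2.09, SE 0.23, adjusted p = 0.000199). COS7 (-2.61, adjusted p = 1.09e-08), HSP26, the heat-shock gene (-2.56, adjusted p = 4.3e-06), PHO12 (-2.52, adjusted p = 0.000362), PHO11 (-2.36, adjusted p = 2.9e-05), GIT1 (-2.18, adjusted p = 1.2e-05) and QCR6 (-1.04, adjusted p = 0.000199) were lower too. COS5 was the only gene called higher in this fit (0.83, adjusted p = 0.00166). The number higher was 1 with limma-voom, 2 with DESeq2 and 3 with only the 2 groups in the fit. Limma called 29 of 5840 genes, and 18 without pho4Δ number 2 or without pho84Δ number 1. Of 20 PHO regulon members 8 were lower, or 15 adjusted over the list alone (camera adjusted p = 1.19e-41, adjusted p = 0.0277 with an estimated correlation). In PHO signalling and constitutive phosphate transport 1 of 14 was lower, PHO4 itself, and 1 adjusted over the list alone (camera adjusted p = 0.00398, adjusted p = 0.271 with an estimated correlation). Stress genes were lower in 4 of 24, or 18 adjusted over the list alone (camera adjusted p = 1.44e-27, adjusted p = 0.103 with an estimated correlation). UME6 and KCS1 did not pass (adjusted p = 1 and 0.994).

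The BY4741 cultures of the 2 series differed in zinc, amino acid, hexose transport and ribosomal protein genes. ZRT1, the high-affinity zinc transporter, stood at 25.1 ± 1.05 against 411 ± 244 RPM (series 2 against series 1, log2 fold change -3.82, SE 0.34, adjusted p = 5.85e-07 in limma, n = 2 against 3), and its low-affinity partner ZRT2 was lower by 1.00 on the log2 scale (adjusted p = 1.54e-06). SRO9, an RNA-binding protein (46.9 ± 4.83 against 11.5 ± 1.59 RPM, 1.94, adjusted p = 2.23e-05), and SNZ1, of vitamin B6 synthesis (1.94, adjusted p = 0.000268), were higher in series 2. SCR1 (-2.77, adjusted p = 0.0001), RGS2 (-2.34, adjusted p = 5.85e-07) and RPL29, a ribosomal protein (-2.18, adjusted p = 4.19e-05), were lower. PHO84 (0.18, adjusted p = 0.837), SPL2 (-0.07, adjusted p = 0.876), UME6 (0.12, adjusted p = 0.523), PHO4 (0.00, adjusted p = 0.987) and KCS1 (0.14, adjusted p = 0.282) did not pass. Of 5927 genes 2196 were called, 1076 higher and 1120 lower, or 1313 without BY4741 number 5. The zinc regulon was lower in 10 of 12, also 10 over the list alone (camera adjusted p = 6.67e-06, adjusted p = 0.362 with an estimated correlation). Amino acid genes under Gcn4 were higher in 19 of 24, or 23 adjusted over the list alone (camera adjusted p = 2e-08, adjusted p = 0.841 with an estimated correlation). Hexose transport was lower in 4 of 10, or 7 adjusted over the list alone (camera adjusted p = 0.0031, adjusted p = 0.362 with an estimated correlation). Cytosolic ribosomal proteins were lower in 50 and higher in 5 of 137, or 50 and 6 adjusted over the list alone (camera adjusted p = 9.8e-06, adjusted p = 0.927 with an estimated correlation), and fry did not call them (adjusted p = 0.117). Series stands here for every difference in day, handling and sequencing, so strain comparisons were made within a series.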

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

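EdgeR with TMM, the kind of test designed before the table was seen, became an alternative when the table was found to hold RPM. It was run with the filter of at least 1 RPM used for limma, not with the edgeR filter by expression named in the design. Alternatives added after the first values were seen were RPM rescaled by TMM, empirical Bayes without a trend, BY4741 of series 2 as the control, and the crossed replicate block. The others were fixed before. The cause was not tested for any change given here. Over all alternatives named genes were sorted by direction and call alone. The size of the fold counted only in the alternative that asked for a log2 fold of at least 1. Both stayed the same in 8312 instances, those of genes called in neither test included. A call was lost in 444 instances and gained in 155. The lost calls include those that only missed the fold of at least 1, such as 20 in ΔP, 18 in ΔU and 18 in ume6Δ. Direction turned in 18 instances of genes called in the main test and in 222 of genes not called there.

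With BY4741 of series 2 as the control, ΔP had 1583 called genes, 148 of the 547 kept, and Tpho84-Tcyc1 had 2019, 181 of the 460 kept. In ΔP these log2 folds turned: AQR1 0.25, DIA1 0.48, RGS2 0.84, YGR035C 0.13, YKR075C 0.20, PUF3 -0.11, HXT1 0.17, FET4 0.18 and IZH1 0.11. In Tpho84-Tcyc1 they were RGS2 0.37, SCR1 0.73, YGR035C 0.12, YKR075C 0.22, GSY1 -0.24, HXT1 0.14, FET4 0.14, IZH1 0.21 and IZH4 0.60. With all 5 BY4741 as controls pho84Δ had 28 called genes. With all 21 libraries in 1 fit ΔP had 1175 and Tpho84-Tcyc1 894. With only the 2 compared groups in the fit the numbers were 144 in ΔP, 1325 in Tpho84-Tcyc1, 8 in pho4Δ, 11 in pho84Δ and 60 between pho4Δ and pho84Δ.

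DESeq2 called 910 genes in ΔP, 839 in Tpho84-Tcyc1, 71 in pho4Δ, 40 in pho84Δ, 78 between ΔP and Tpho84-Tcyc1 and 63 between pho4Δ and pho84Δ. EdgeR with TMM, on the genes that passed the filter used for limma, called 530, 508, 2761, 2143, 13 and 14 genes in ΔP, Tpho84-Tcyc1, ΔU, ume6Δ, pho4Δ and pho84Δ. Limma-voom called 9 in pho84Δ. Without a filter 349 were called in ΔP and 8 in pho4Δ, and without the trend 8 in pho4Δ. A fold of at least 1 on the log2 scale left 39 in ΔP, 45 in Tpho84-Tcyc1, 278 in ΔU, 424 in ume6Δ, 8 in pho4Δ, 9 between ΔP and Tpho84-Tcyc1, 369 between ume6Δ and ΔU, and 167 between the BY4741 groups.

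At adjusted p under 0.01, ΔP and Tpho84-Tcyc1 shared 4 rises and 45 falls, and ΔU and ume6Δ 450 and 142. ΔU and pho4Δ shared 0 rises, ume6Δ and pho4Δ 1 rise and 1 fall, and ume6Δ and pho84Δ 7 rises.

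With an estimated correlation camera called 0 lists in ΔP, Tpho84-Tcyc1, ΔU, pho4Δ, pho84Δ and between the BY4741 groups. It called 2 in ume6Δ, 2 between ΔP and Tpho84-Tcyc1, 2 between ume6Δ and ΔU and 1 between pho4Δ and pho84Δ. With fry 14 lists were called in ΔU, 4 in pho4Δ, 0 in pho84Δ and 2 between ΔP and Tpho84-Tcyc1.

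With 1 library left out, and a lone library assumed to vary like the other groups, called genes ran from 62 to 1867 in ΔP, 86 to 327 in Tpho84-Tcyc1, 6 to 63 in pho4Δ and 11 to 171 in pho84Δ. Between mutants they ran from 12 to 546 (ΔP and Tpho84-Tcyc1) and 18 to 27 (pho4Δ and pho84Δ), and between the BY4741 groups from 1313 to 1847. Called lists ran from 5 to 10 in ΔP, 5 to 10 in pho4Δ and 3 to 5 in pho84Δ. The direction of the Gcn4 list in pho4Δ turned without BY4741 number 5 (adjusted p = 0.862) and pho4Δ number 2 (adjusted p = 9.24e-05), its values running from 1.46e-27 to 0.862. In pho84Δ it turned without BY4741 number 5 (adjusted p = 0.367), from 2.16e-05 to 0.367. Ribosomal proteins between ΔP and Tpho84-Tcyc1 turned without ΔP number 3 (adjusted p = 0.0423), from 3.83e-18 to 0.575.

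Replicate number as a replicate block, with only pho4Δ and pho84Δ in the fit, gave 64 called genes, and the crossed block gave 168. In series 1 the replicate block gave 661 in ΔP, 474 in Tpho84-Tcyc1 and 24 between them, and between ume6Δ and ΔU 2776. The same numbers do not mark shared handling in the texts, and the r between deviations of same-numbered libraries gave no uniform sign. It ran from -0.0624 to 0.281 for BY4741 of series 1 and ΔP, -0.225 to 0.247 for BY4741 of series 1 and Tpho84-Tcyc1, and 0.0105 to 0.154 for ΔP and Tpho84-Tcyc1. In series 2 it ran from -0.0202 to 0.104 for ΔU and ume6Δ, 0.102 to 0.162 for ΔU and pho4Δ, -0.0774 to -0.009 for ΔU and pho84Δ, -0.0773 to 0.0831 for ume6Δ and pho4Δ, and -0.15 to -0.0709 for ume6Δ and pho84Δ, and was -0.188 for pho4Δ and pho84Δ. No paired analysis was possible between BY4741 of series 2 and the mutants of that series because BY4741 carries numbers 4 and 5 and the mutants 1 to 3.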

Other observations

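Tests of the shared falls, of PHO84 across cultures and of a swapped ume6Δ library, and the extra lists, were chosen after values were seen. In ΔU, genes of drug efflux under Pdr1 and Pdr3 were higher than in BY4741 of series 2. PDR5, a drug efflux pump, stood at 2195 ± 158 against 444 ± 4.46 RPM (2.30, adjusted p = 1.48e-10 in limma), PDR15, its paralog, at 175 ± 32.9 against 32.2 ± 4.43 RPM (2.39, adjusted p = 3.09e-08), and PDR3, a transcription factor of these pumps, at 108 ± 0.940 against 32.1 ± 2.99 RPM (1.72, adjusted p = 4.47e-09). Of 12 such genes 11 rose, and PDR18 did not pass (-0.05). Hypoxic genes moved the other way, 7 of 13 having fallen and 1 risen. TIR1 (-2.95) and ANB1, a translation factor paralog (2.29 ± 0.219 against 16.5 ± 10.8 RPM, -2.26, adjusted p = 2.29e-05), fell and COX5B, a cytochrome oxidase subunit, rose (0.37, not called with all 5 BY4741 as controls, adjusted p = 0.121). Targets of Leu3 fell in 4 of 6 cases, BAT1, an aminotransferase gene, by 1.05 on the log2 scale (adjusted p = 9.69e-06), and LEU4 did not pass (0.44, adjusted p = 0.0543). All 7 of 7 retrograde-response genes rose, IDH1 by 1.66, ACO1 by 1.34 and CIT2 by 1.05. In ume6Δ, not tested against ΔU for these lists, there were 7 rises and 1 fall of drug efflux, 6 and 2 of hypoxic genes, 0 and 3 of Leu3 targets, and 1 and 1 of retrograde genes.

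The Ty3 element YGR109W-B was high in 7 libraries of series 2, those of ume6Δ, pho4Δ and pho84Δ, at 30.1 to 43.2 RPM. BY4741 of that series held 2.59 and 0.249 RPM, and every other library 0.574 RPM or less. Another Ty3 feature, YIL082W-A, stood apart in ume6Δ alone, at 149.7, 151.2 and 156.9 RPM. It was at 55.75 and 60.05 RPM in pho4Δ, 61.75 and 61.95 RPM in pho84Δ, and 50.55 and 60.06 RPM in BY4741 of series 2. No biological explanation was tested for either feature, and how far Ty3 copies share reads was not measured.

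Hypothesis: the wide response of ΔU follows from altered mitochondrial function. If so, the retrograde-response genes, which rise when mitochondrial function is lost, should be higher, and their median log2 change was 1.05. That list was chosen after values were seen, so its median is not an independent test of the hypothesis. Scaling is unlikely to be the whole cause, since the number called with TMM was 0.948 of that reported. TMM kept 2129 of the 2904 called genes, however, and moved the split from 2133 rises and 771 falls to 1358 and 1396, so the excess of rises depends on scaling. The lowest ratio with 1 library left out was 0.757, without BY4741 number 5. The lone control is there assumed to vary like the other groups, and under that assumption a single library is unlikely to set the response. Iron, drug efflux and stress genes such as FET3, PDR5 and HSP12 rose in the same cultures, so the retrograde genes may not be the source of the rest, and respiration was not measured.

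Hypothesis: the falls shared by ΔP and Tpho84-Tcyc1 belong to the BY4741 cultures of series 1 and not to the mutations. For 50 genes chosen on BY4741 number 1 and 2, BY4741 of series 2 lay lower than BY4741 number 3 by a median of -1.09 on the log2 scale, 98% of them lower. Over the 142 shared falls the mutants of series 1 differed from BY4741 of series 2 by a median of -0.0746, with quartiles of -0.28 and 0.14. These genes were chosen because the same mutants lay below BY4741 of series 1, which fixes where the mutants lie, so a difference between the series for every strain stays open. HXT2 and DBP2 remained lower in both mutants with BY4741 of series 2 as the control, so the hypothesis may hold for many of the genes and not for these. ZRT1, at 411 ± 244 RPM in BY4741 of series 1, would be a gene to measure in new cultures.

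Hypothesis: cultures of a strain differ in PHO84 because part of the PHO regulon moves with it from culture to culture. Over 17 libraries, deviations of PHO84 from the group mean followed the mean deviation of SPL2, PHO12, PHO11, VTC3 and VTC4 with r of 0.839, but these 5 were picked after values were seen, so that r restates the observation. For the mean of the 14 PHO regulon members not picked r was 0.709 (permutation p = 0.0203), and for single members from -0.143 in PHM7 to 0.803 in CTF19. The ume6Δ cultures weigh most in these r, with PHO84 deviations of -2.15, 1.02 and 1.12, against -0.615 to 0.504 in the other groups. Leaving out the 2 farthest libraries, both of ume6Δ, was tried only for the 5 picked genes (r of 0.862). PHO5 did not follow in BY4741 of series 1, at 17.1, 17.9 and 15.9 RPM where PHO84 was at 157, 135 and 76.2 RPM. A swap of ume6Δ number 1, which had the lowest PHO84 of its group (8.41 RPM), is unlikely, since UME6 stood at 0.343 RPM there and its correlation with another ume6Δ library was 0.995. Measuring PHO84 and SPL2 in more cultures of 1 strain would test it.

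Splits of the 6 libraries of a comparison into other groups of 3 were too few to measure chance. Of 10 splits, 1 called as many genes as the real one in ΔP against BY4741, 1 in Tpho84-Tcyc1 against BY4741, 1 in ΔP against Tpho84-Tcyc1 and 1 in ume6Δ against ΔU, each time the real one itself.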
